A study of Rattus norvegicus with 31 samples.

How the data were processed

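Gastrocnemius, a mixed but mostly fast calf muscle, was taken from 31 female Sprague Dawley rats on chow. The rats were controls or carried a knockout of Ucp1, the uncoupling protein of brown fat mitochondria, and were kept either at room temperature or at 4 °C. Per the labels the rats were 7 months old and the period lasted 14 days. The groups were control at room temperature (n = 8), knockout at room temperature (n = 7), control in the cold (n = 8) and knockout in the cold (n = 8), and each animal gave 1 library. The labels number every animal separately, so nothing pairs animals across groups, and they name no batch, litter or cage. Libraries are named here by group and animal number.

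Total RNA was made into libraries with a QuantSeq 3' kit, which reads a tag near the 3' end of each polyadenylated transcript, so a count does not depend on transcript length but does depend on where the 3' end is annotated. The deposited table of raw values holds counts of reads per gene that the authors made, and a deposited table of normalized values holds signal, the authors' counts divided by DESeq2 size factors. Per the submitters' processing notes the build was Rnor 6.0 and the normalization was done with DESeq2 1.22.2; the aligner, the counting tool and the strand setting are not given in the sources used here. The deposited normalized signal equalled the raw counts divided by 1 size factor per library to a relative difference of 5.24e-10, so only the raw counts were used for tests. Both tables list 11289 genes, and the lowest total of a listed gene over the 31 libraries was 93 counts, so a filter on low counts had been applied before deposition. Reads were counted without molecular identifiers as far as the sources show, so counts include PCR copies. Reads of near-identical genes, such as the copies of Hba-a2 and Rpl30, may be assigned to either copy.

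Gene symbols came from the deposited table for 10200 identifiers and from a RefSeq gene table of assembly GRCr8 for 169 more; 920 had no symbol, and 38 shared a symbol with another identifier. GRCr8 served for names, for gene positions and for the order of genes along chromosomes, while the counts rest on Rnor 6.0. Total counts per library ran from 6.56 to 11.9 M counts, with a mean of 9.30 ± 1.26 M counts (SD, n = 31). No 2 libraries of a group matched within sampling noise: the lowest chi-square per degree of freedom over 105 pairs within groups was 5.00.

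Differences were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 10082 genes, and a quasi-likelihood model with 1 mean per group and no other term was fitted to all 31 libraries, with 27 residual degrees of freedom. The contrasts were cold against room temperature in each genotype, knockout against control at each temperature, the difference between the cold effects (interaction) and the knockout effect averaged over temperatures. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 10082 genes within each contrast, with a threshold of 0.05; changes are log2 fold changes with the standard error (SE) of the fit, taken as the size of the change over the square root of its F value. Levels are CPM after TMM. A log2 level uses a prior count of 2. P-values measure a difference against the spread between animals of a group, which holds an unrecorded batch only where it cuts across groups. Animal numbers run in blocks by group, so a batch that followed them could not be told apart from the group difference.

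The contrasts, 26 gene lists and the rule for naming genes were fixed before the data were examined. The rule names, for each contrast, the 10 highest and 10 lowest changes among passing genes with a symbol and a mean of at least 5 CPM; the 5 smallest p-values where fewer than 5 genes passed; up to 4 members of each list by p; and 11 fixed genes, of which 8 were tested here. Of the fixed genes Myh4, Atp2a1 and Fgf21 were not tested, so the fast fibre list was measured without Myh4 and Atp2a1. Where length was limiting, the first genes by that ranking are given. Ucp1 itself, which was to check the labels, is not analysed here, so genotype rests on the labels alone. Lists were tested against the other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 26 lists within a contrast. Camera with a correlation estimated from the data, and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. The estimated correlation had a median over the lists of 0.192 to 0.194 per contrast, far above the preset 0.01. P-values at the preset correlation are therefore too small for lists whose genes vary together, and a pass there alone is weak. Counts of passing members are given over all genes and adjusted over the list alone.

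On simulated data with the same depths and dispersions, in which 67, 67 and 66 genes changed by 1.5, 2 and 4-fold, the fit recovered 20.9%, 65.7% and 93.9% for cold in controls and 28.4%, 55.2% and 100% for cold in knockouts. Recovery was 32.8%, 56.7% and 100% for the knockout at room temperature, 25.4%, 80.6% and 98.5% for the knockout in the cold, and 47.8%, 89.6% and 97.0% for the knockout averaged over temperatures. For the interaction it was 4.48%, 23.9% and 86.4%. Between 2 and 9 unchanged genes were called per contrast. The simulation drew genes independently, without the structure that real libraries share, so its recoveries and false calls may not hold for them. Other splits of the real animals called up to 75 genes for cold in knockouts and 1490 for the knockout averaged over temperatures.

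Alternatives were scaling by DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, fits to only the groups compared, limma voom with sample quality weights, robust quasi-likelihood, library sizes without the 20 most abundant genes, 1 surrogate variable from sva 3.50.0, and each library left out in turn. Added after the data were seen were leaving out control animals 1 and 2 at room temperature, leaving out the 7 libraries below the widest gap at the low end of the first principal component, and that component as a covariate. Neither scaling alternative turned the direction of a passing gene named here. The largest shift of the median change of all genes under them was -0.0265 on the log2 scale.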

Results

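The transcriptome of the gastrocnemius was measured in 8 control and 7 Ucp1 knockout rats at room temperature and in 8 control and 8 knockout rats after 14 days at 4 °C. Rats without Ucp1 lack the uncoupling protein through which brown fat makes heat, and the comparisons ask how muscle gene expression responded to cold with and without it. Mean total counts were 8.83 ± 1.13, 9.26 ± 1.29, 9.07 ± 0.933 and 10.02 ± 1.54 M (SD) in control and knockout rats at room temperature and control and knockout rats in the cold. Transcripts encoded in mitochondrial DNA took 12.5 ± 1.15%, 12.4 ± 1.59%, 10.3 ± 0.989% and 9.43 ± 1.59% of the counts in the same order. The first principal component of log2 levels held 35.3% of the variance and the second 14.1%. Control animals 1 and 2 at room temperature stood apart on the second component, with scores of -62.3 and -79.8. Their level of the adipocyte hormone Adipoq was 0.630 and 0.313 CPM, against 10.7 to 31.5 CPM in the other room temperature controls. The highest loadings of named genes on the second component were, in order, those of Retn, Adipoq, Tnmd, Chad and Cilp2, so fat markers were not the only genes at that end.

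In control rats, cold raised genes of slow muscle fibres and of developing or denervated muscle. Myh7, the slow myosin heavy chain (GRCr8 chromosome 15, 32416525 to 32439851), went from 2254 ± 606 to 4430 ± 647 CPM (SD, n = 8 and 8), a log2 change of 0.97 ± 0.16 (SE; adjusted p = 0.00164). Atp2a2, the calcium pump of slow-fibre sarcoplasmic reticulum (GRCr8 chromosome 12, 39733519 to 39782942), rose by 1.07 ± 0.18 (adjusted p = 0.00415), from 537 ± 131 to 1127 ± 157 CPM. Myh3, the embryonic myosin heavy chain, rose by 2.23 ± 0.42 (adjusted p = 0.00986) and Ucp2, a mitochondrial carrier related to Ucp1, by 1.28 ± 0.26 (adjusted p = 0.0136). The immediate early transcription factor Fos fell from 31.3 ± 26.4 to 7.34 ± 3.59 CPM, a log2 change of -2.09 ± 0.44 (adjusted p = 0.0145).

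In the list of slow and oxidative fibre genes, 5 of 15 measured members rose and 10 did not pass, with 8 higher when adjusted over the list alone. Besides Myh7 and Atp2a2, Tpm3, the slow tropomyosin, rose by 1.08 ± 0.21 and Myoz2, a Z-disc protein of slow fibres, by 0.92 ± 0.17. The list as a whole was higher (camera adjusted p = 2.69e-13; adjusted p = 0.0131 with an estimated correlation). In the list of satellite cell, regeneration and denervation genes, 2 of 13 rose, and 6 were higher when adjusted over the list alone. Those 2 were Myh3 and Chrnd, the delta subunit of the muscle acetylcholine receptor (1.19 ± 0.27). That list was higher too (camera adjusted p = 0.00187; adjusted p = 0.0131 with an estimated correlation). Of 12 mitochondrially encoded transcripts, 2 fell, Mt-nd4l (-1.01 ± 0.21) and Mt-nd5 (-0.62 ± 0.14), both subunits of respiratory complex I. When adjusted over the list alone 5 were lower (camera adjusted p = 1.15e-05; adjusted p = 0.193 with an estimated correlation). Of 19 contraction-induced immediate response genes, 3 fell, Fos, Egr1 (-1.46 ± 0.37) and Jun (-0.65 ± 0.16). Adjusted over the list alone, 3 were lower and 1, the calcineurin inhibitor Rcan1, was higher (camera adjusted p = 1.14e-04; adjusted p = 0.302 with an estimated correlation). Levels of this list followed the first principal component over the 31 libraries (r = 0.803). With that component as a covariate the list stood at camera adjusted p = 0.00401, and the calls of Fos, Egr1 and Jun held.

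Of 34 genes of fatty acid uptake and oxidation only Ucp2, which is not an enzyme of oxidation, passed. In that list 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00237; adjusted p = 0.267 with an estimated correlation). Of 22 genes of sarcoplasmic reticulum calcium cycling only Atp2a2 passed, and 2 were higher when adjusted over the list alone (camera adjusted p = 0.0285; adjusted p = 0.468 with an estimated correlation). Of 20 genes of endoplasmic reticulum stress and amino acid response 0 passed. Among them 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00187, higher; adjusted p = 0.227 with an estimated correlation). Of 29 extracellular matrix genes 2 rose, Bgn (1.05 ± 0.24), a small proteoglycan, and Lox (1.01 ± 0.23), the collagen cross-linking oxidase. Of the matrix genes 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0327; adjusted p = 0.641 with an estimated correlation). Of 14 lipogenesis genes 0 passed over all genes. Thrsp (1.36 ± 0.36), Fasn (1.58 ± 0.43) and Scd (2.13 ± 0.61) were higher and Me1 lower when adjusted over the list alone (camera adjusted p = 0.0330, higher; adjusted p = 0.302 with an estimated correlation). Without control animals 1 and 2 at room temperature Thrsp (1.10), Fasn (1.35) and Scd (1.74) stood at adjusted p = 0.0348 each over the list alone, and Me1 did not pass. With the first principal component as a covariate Thrsp (1.20), Fasn (1.54) and Scd (2.16) passed over all genes (adjusted p = 0.0371, 0.0390 and 0.0377). Without the 7 libraries at the low end of that component they did not (adjusted p = 0.109, 0.0853 and 0.188).

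Markers of other cell types were examined beside these lists. Of 20 immune markers 2 rose, the macrophage receptor Cd163 (0.99 ± 0.20) and S100a8 (2.81 ± 0.63), a protein of neutrophils. Among immune markers 5 were higher when adjusted over the list alone (camera adjusted p = 6.75e-08; adjusted p = 0.193 with an estimated correlation). Of 6 erythrocyte markers 0 passed and 4 were higher when adjusted over the list alone (camera adjusted p = 8.94e-04, higher; adjusted p = 0.193 with an estimated correlation). Of 13 white adipocyte markers 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.00729, higher; adjusted p = 0.468 with an estimated correlation). That difference rested on control animals 1 and 2 at room temperature, without which camera gave adjusted p = 0.689. Of 12 endothelial markers 1 fell, Cdh5 (-0.64 ± 0.16), the junction protein VE-cadherin, also when adjusted over the list alone (camera adjusted p = 0.0285; adjusted p = 0.468 with an estimated correlation). Without the same 2 animals the endothelial and extracellular matrix lists did not pass camera either (adjusted p = 0.194 and 0.907).

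By the naming rule, the other genes with the largest increases in cold controls were Ctxn3 (1.60 ± 0.38), the secreted phospholipase Pla2g12a (1.41 ± 0.32), the protease inhibitor Cst7 (1.31 ± 0.30), Parm1 (1.27 ± 0.20), the matrix protein Fbln1 (1.23 ± 0.31), the M-band protein Myom1 (1.17 ± 0.27) and the fructose transporter Slc2a5 (1.14 ± 0.23). The largest decreases after Fos and Egr1 were in Car4, a carbonic anhydrase (-1.17), Wsb1 (-1.12), Mt-nd4l, Mdfic (-0.99), Pik3cd, a kinase subunit of leukocytes (-0.93), Arhgef15 (-0.76), Jun and Rfc4 (-0.65). Among the genes fixed in advance, Sln, the sarcolipin that uncouples the calcium pump, went from 7.61 ± 5.48 to 26.5 ± 27.6 CPM without passing (1.80 ± 0.56, adjusted p = 0.114). Nor did the muscle uncoupling protein Ucp3 (-0.66 ± 0.32), the fatty acid importer Cpt1b (0.53 ± 0.15), the coactivator Ppargc1a (-0.12 ± 0.31), the kinase Pdk4 (0.14 ± 0.44) or the calcium release channel Ryr1 (-0.09 ± 0.21) pass.

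Over all 10082 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 86 genes in cold controls, 60 higher and 26 lower, and DESeq2 called 220. With 1 surrogate variable most calls were lower, 224 against 159 higher, and with the first principal component as a covariate 219 against 160. At an unadjusted p under 0.05 there were 1434 genes, where 504 are expected by chance. Without control animals 1 and 2 at room temperature 38 genes passed, 29 of them among the 86. Of 52 passing genes named or called in both genotypes 22 still passed. Ucp2 (1.25, adjusted p = 0.0512), Ctxn3 (1.80), Pla2g12a (1.21), Cst7 (1.25), Fbln1 (0.93), Myom1 (1.02), Bgn (0.88), Lox (0.83), Cd163 (0.79), S100a8 (2.62) and Bhlhe41 (0.80) no longer passed then. Nor did Egr1 (-1.34), Jun (-0.72), Wsb1 (-0.84), Cdh5 (-0.58), Arhgef15 (-0.46), Rfc4 (-0.39) or Pik3cd (-0.34). Without the 7 libraries at the low end of the first principal component 33 of the 52 passed, with Egr1 (-1.11, adjusted p = 0.228), Pla2g12a (1.28, adjusted p = 0.0899), Lox (1.05, adjusted p = 0.0853) and Car4 (-1.14, adjusted p = 0.0539) among those lost, and 16 passed without either set of libraries and in all single omissions. Without control animals 1 and 2 the slow fibre and satellite cell lists stood at adjusted p = 0.0662 with an estimated correlation. Leaving out single libraries ended the call of Fbln1 and Jun in 22 of 31 cases each and of Egr1 and Cdh5 in 20 each. It ended 0 calls among Myh7, Atp2a2, Myh3, Fos, Mt-nd4l, Parm1 and Slc2a5.

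**Figure D1:**
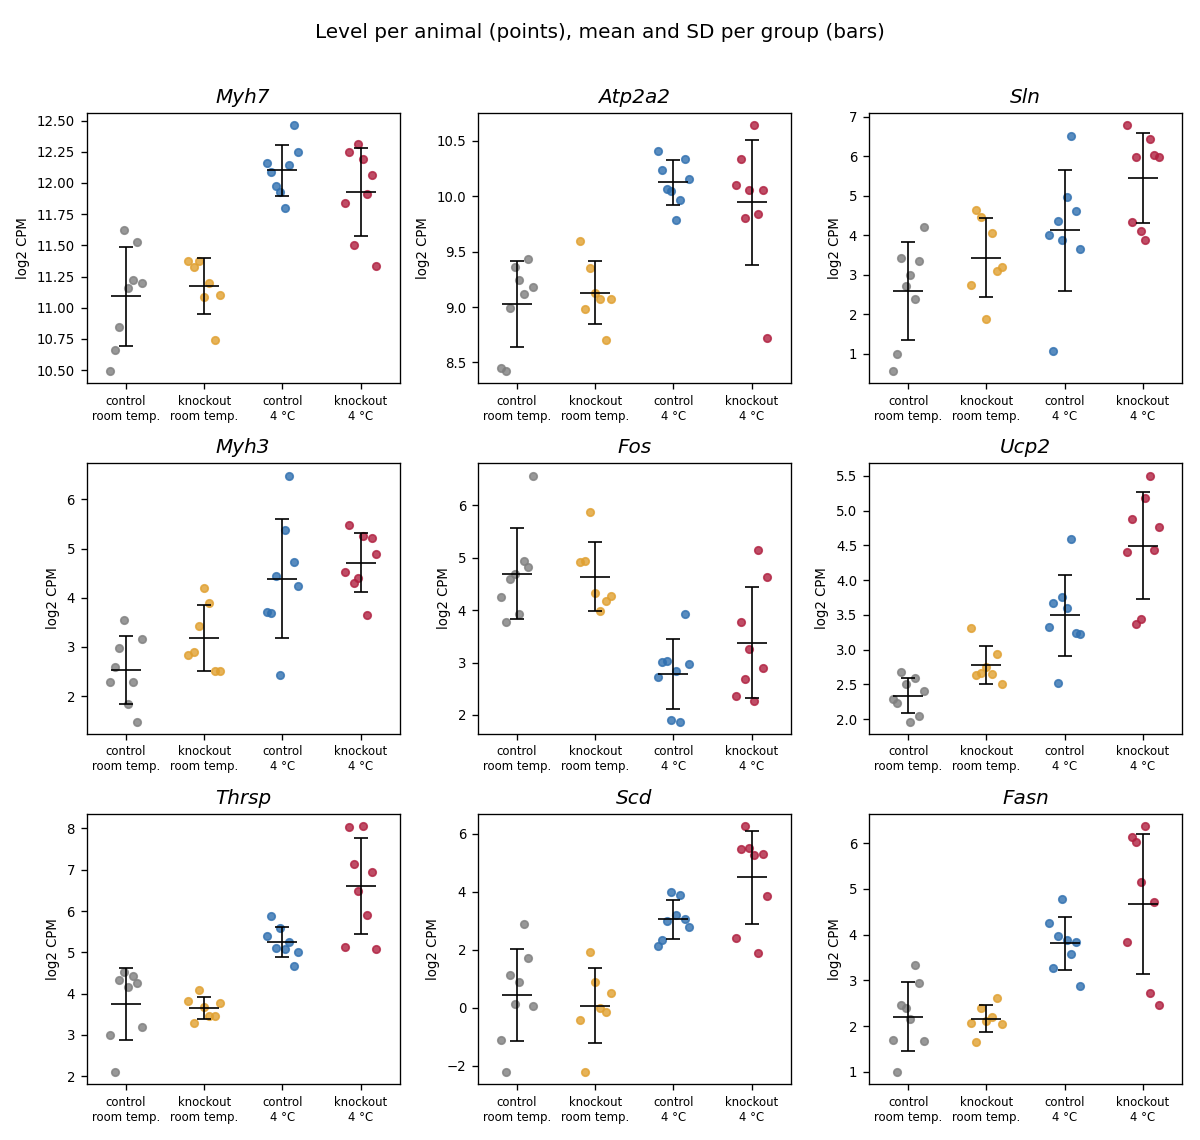
Log2 CPM of 9 genes in each animal (points) with the mean and SD (bars) of control and knockout rats at room temperature and at 4 °C. All 8 cold controls lay above all 8 room temperature controls for Myh7 (lowest 11.80, highest 11.62) and Atp2a2 (9.79 and 9.44). Cold animals lay above room temperature animals for Thrsp in controls (4.67 and 4.52) and in knockouts (5.08 and 4.09). In knockouts the 2 temperatures overlapped for Scd (lowest cold 1.88, highest room temperature 1.93) and Fasn (2.46 and 2.60).

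In knockout rats the 3 largest increases in the cold, among passing genes with a symbol and a mean of at least 5 CPM, were in lipogenic genes. Scd, the desaturase that makes oleate (GRCr8 chromosome 1, 253218968 to 253232101), went from 1.21 ± 1.18 to 33.2 ± 24.6 CPM (SD, n = 7 and 8), a log2 change of 4.80 ± 0.71 (SE; adjusted p = 2.68e-04). Thrsp, a thyroid hormone responsive factor that promotes lipogenesis (GRCr8 chromosome 1, 161134640 to 161138964), went from 12.6 ± 2.46 to 127 ± 93.6 CPM (3.33 ± 0.40, adjusted p = 1.77e-05), and Fasn, fatty acid synthase, from 4.33 ± 0.927 to 38.0 ± 30.5 CPM (3.13 ± 0.47, adjusted p = 2.68e-04). Slow fibre genes rose here too, Myh7 by 0.78 ± 0.16 (adjusted p = 0.00898) and Atp2a2 by 0.88 ± 0.19 (adjusted p = 0.0131). Mt-atp8, an ATP synthase subunit encoded in mitochondrial DNA, fell from 2009 ± 678 to 760.2 ± 200 CPM (-1.40 ± 0.25, adjusted p = 0.00195). Mt-atp6, another such subunit, changed by -0.23 ± 0.15 without passing (adjusted p = 0.531). Counts per gene do not show from which mRNA a read came, so the fall of Mt-atp8 need not be that of an mRNA.

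Of 14 lipogenesis genes 4 rose and 10 did not pass, the fourth being Acly, which makes cytosolic acetyl-CoA (0.97 ± 0.22). Among lipogenesis genes 7 were higher when adjusted over the list alone (camera adjusted p = 4.37e-08; adjusted p = 0.00909 with an estimated correlation). White adipocyte markers moved with them: 1 of 13 rose, the hormone Retn (2.41 ± 0.54), and Adipoq stood at 47.9 CPM against 17.3 CPM in room temperature knockouts without passing. Among adipocyte markers 6 were higher when adjusted over the list alone (camera adjusted p = 6.47e-05; adjusted p = 0.217 with an estimated correlation). Of 15 slow fibre genes 4 rose, among them Myoz2 (0.85 ± 0.17) and Tnni1, the slow troponin I (0.60 ± 0.14). Among slow fibre genes 10 were higher when adjusted over the list alone (camera adjusted p = 1.75e-10; adjusted p = 0.0235 with an estimated correlation). Of 12 mitochondrially encoded transcripts 3 fell, Mt-atp8, Mt-nd4l (-1.14 ± 0.21) and Mt-nd5 (-0.75 ± 0.14). Adjusted over the list alone, 8 were lower (camera adjusted p = 8.52e-13; adjusted p = 0.0171 with an estimated correlation). In the satellite cell, regeneration and denervation list 1 of 13 rose, Chrnd (1.61 ± 0.28), while Myh3 (1.52 ± 0.42, adjusted p = 0.0584) did not pass. Within this list 6 were higher when adjusted over the list alone (camera adjusted p = 0.00350; adjusted p = 0.0171 with an estimated correlation).

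Of 20 endoplasmic reticulum stress and amino acid response genes 2 rose in cold knockouts, Mthfd2 (1.40 ± 0.30), an enzyme of mitochondrial folate metabolism, and Sdf2l1 (0.74 ± 0.19), a chaperone cofactor. Among stress response genes 6 were higher when adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.350 with an estimated correlation). Of 21 atrophy and autophagy genes 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0323, higher; adjusted p = 0.693 with an estimated correlation). Of 6 erythrocyte markers 2 rose, Alas2 (1.36 ± 0.34), the heme synthesis enzyme of red cells, and the globin Hbb-b1 (1.15 ± 0.30). Among erythrocyte markers 4 were higher when adjusted over the list alone (camera adjusted p = 4.37e-05; adjusted p = 0.0480 with an estimated correlation). Of 20 immune markers 1 rose, Cd163 (1.02 ± 0.21), with 2 higher when adjusted over the list alone (camera adjusted p = 0.00322; adjusted p = 0.581 with an estimated correlation).

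By the same rule the remaining genes with the largest increases in cold knockouts were Ppp1r14c (3.005 ± 0.66), a phosphatase inhibitor, Crym (2.51 ± 0.42), which binds thyroid hormone in the cytosol, and the zinc transporter Slc30a2 (2.34 ± 0.52). They were followed by Ctxn3 (1.94 ± 0.39), Ucp2 (1.89 ± 0.27) and Agt (1.69 ± 0.34), the precursor of angiotensin. The largest decreases were in the phosphatase Dusp8 (-1.61 ± 0.26), Mt-atp8, Mss51 (-1.23 ± 0.22), Rnf150 (-1.16 ± 0.17), the linker histone Hist1h1e (-1.16) and Mt-nd4l. Next came Prkaa2 (-0.95), a catalytic subunit of AMP-activated kinase, the potassium channel Kcna7 (-0.92), Lcor (-0.84) and Med13 (-0.80). Sln went from 12.8 ± 8.14 to 55.2 ± 35.3 CPM and did not pass (2.11 ± 0.58, adjusted p = 0.0570). Ucp3 (-0.13 ± 0.33), Cpt1b (0.39 ± 0.16), Ppargc1a (-0.51 ± 0.32), Pdk4 (-0.91 ± 0.42) and Ryr1 (-0.13 ± 0.22) did not pass either.

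By edgeR's quasi-likelihood test 139 genes passed in cold knockouts, 103 higher and 36 lower, and DESeq2 called 328. The balance turned without knockout 15 at room temperature, to 72 higher and 92 lower, and without knockout 10 it was 86 and 72. At an unadjusted p under 0.05 there were 1444 genes, where 504 are expected by chance. A fit to only the 15 libraries compared called 53 genes, 45 of them among the 139. Without the 7 libraries at the low end of the first principal component the slow fibre (adjusted p = 0.125), lipogenesis, mitochondrial, satellite cell and erythrocyte lists (adjusted p = 0.103 each) no longer passed with an estimated correlation. That setting called 146 genes, 79 of them among the 139, and kept 44 of 60 calls of genes named or called in both genotypes. Tnni1 (0.55, adjusted p = 0.0678), Mthfd2 (1.38, adjusted p = 0.0505), Sdf2l1 (0.79, adjusted p = 0.0794), Bgn (0.80, adjusted p = 0.108) and Lcor (-0.85, adjusted p = 0.0864) were among those it ended. Thrsp (2.71), Fasn (2.51) and Crym (1.82) kept their calls there with folds smaller by over 1.5 times. The calls of Scd, Thrsp, Fasn, Crym, Ucp2, Mt-atp8, Chrnd and Myh7 held without any single library. Without cold knockout 29 Ppp1r14c (1.83, adjusted p = 0.0723) and Slc30a2 (1.49, adjusted p = 0.0593) lost their calls, Slc30a2 also without knockout 14 at room temperature, and Crym fell to 1.72 without cold knockout 25 with its call kept. The call of Med13 ended in 17 of 31 omissions, of Hbb-b1 in 19, of Kcna7 in 11, of Hist1h1e, Bgn and Sdf2l1 in 10 each, and of Acly, Atp2a2 and Retn in 1 each.

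In cold knockouts the contraction-induced response (camera adjusted p = 0.730), fatty acid oxidation (0.375), calcium cycling (0.0707), extracellular matrix (0.0635) and endothelial markers (0.297), which passed in controls, did not pass. Several fixed lists passed camera at the preset correlation in neither genotype. These were fast glycolytic fibre genes (13 measured), the tricarboxylic acid cycle (18), nuclear-encoded oxidative phosphorylation subunits (75), glycolysis and glycogen metabolism (24), creatine metabolism (7), cholesterol synthesis (15), heat shock proteins (20), the circadian clock (15), the interferon response (17), adrenergic and thyroid hormone signalling (12), brown adipocyte markers (5) and smooth muscle and nerve sheath markers (13). The fast fibre genes measured leave out Myh4 and Atp2a1. Single members passed in 2 of these lists. Gbe1, the glycogen branching enzyme (0.60 ± 0.14), and Phka1, a subunit of phosphorylase kinase (0.59 ± 0.14), rose in cold knockouts, and the clock repressor Bhlhe41 rose in cold controls (0.97 ± 0.24). The calls of Gbe1, Phka1 and Bhlhe41 ended in 5, 8 and 12 of 31 single omissions, and without the 7 low-end libraries (adjusted p = 0.0735, 0.0991 and 0.135).

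**Figure D2:**
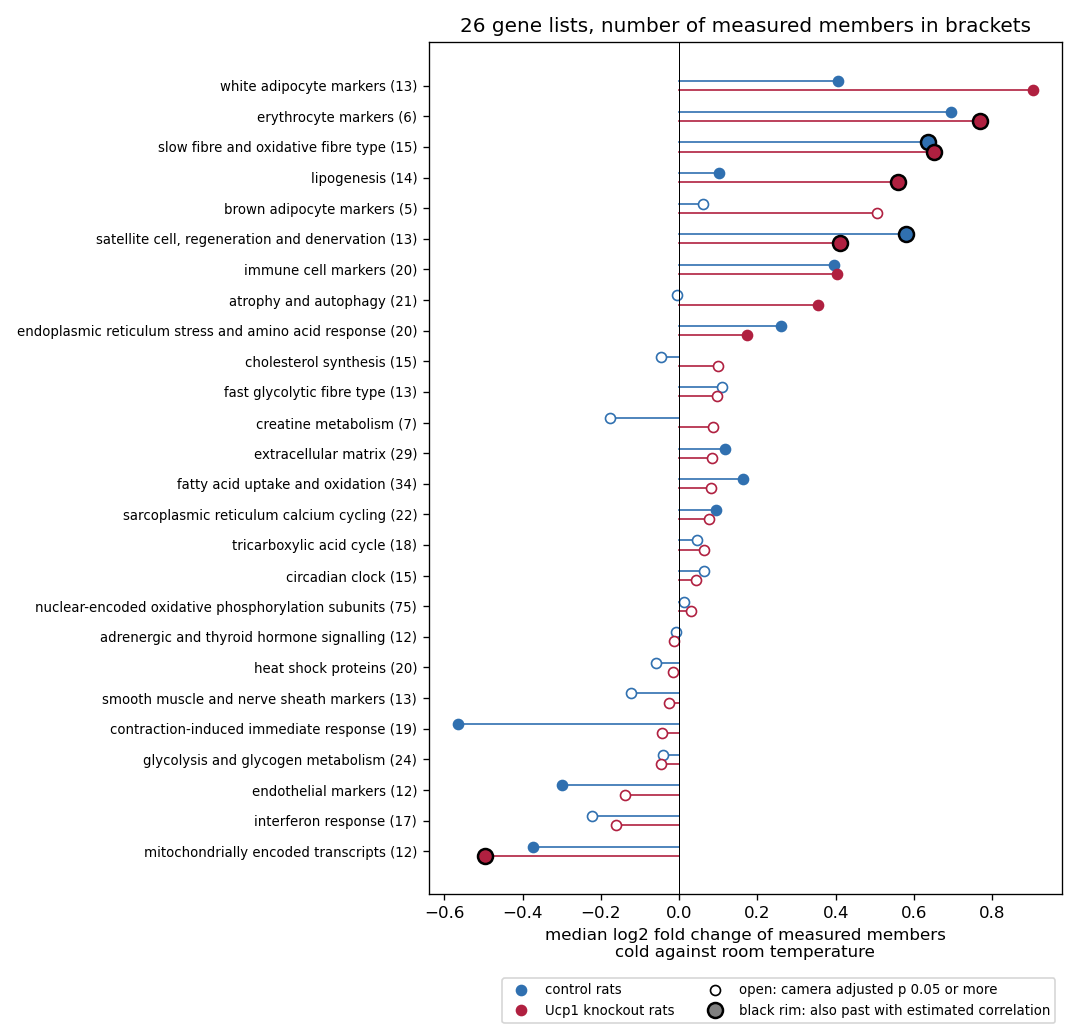
Median log2 fold change of cold against room temperature for the measured members of 26 gene lists in control (blue) and Ucp1 knockout rats (red), with the number of measured members in brackets. Filled points passed camera at the preset correlation, 13 in controls and 9 in knockouts, and points with a black rim also passed with an estimated correlation, 2 and 5.

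The cold responses of the 2 genotypes were compared directly. Across the 10082 genes the log2 changes correlated with Pearson's r of 0.353 and Spearman's rho of 0.289. The jackknife SE of that r over the 31 libraries was 0.232, so r lay within 2 SE of 0. Across the 190 genes called in either genotype r was 0.786. These are correlations across genes, which are not independent replicates, and the second rests on genes selected for their change. Of the 190 genes 174 moved in the same direction. In all 31 genes were called higher in both genotypes where 0.613 are expected of independent lists, and 4 were called lower in both where 0.0928 are expected. Among those 35 were Myh7, Atp2a2, Myoz2, Ucp2, Chrnd, Bgn, Cd163, Mt-nd4l and Mt-nd5.

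**Figure D3:**
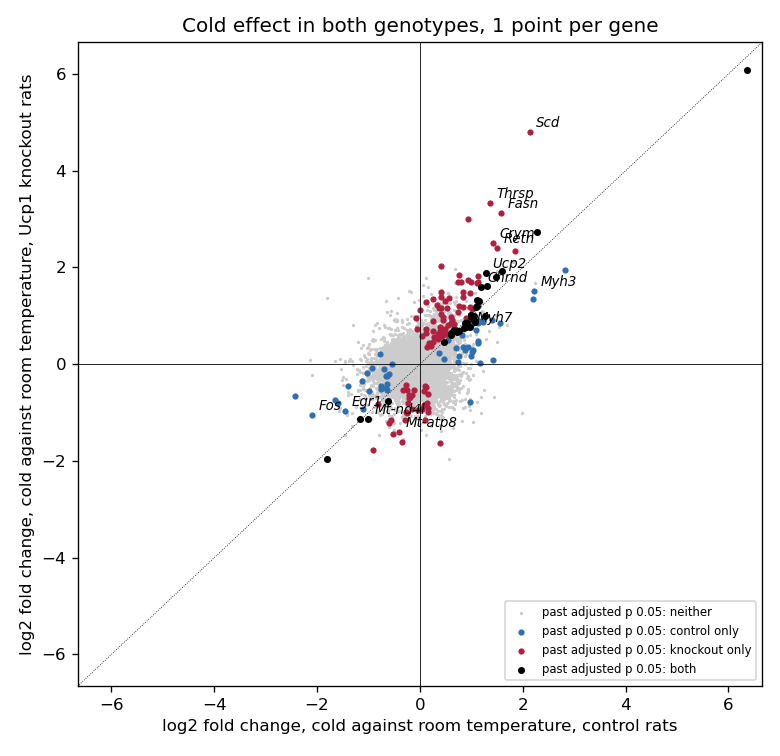
Log2 fold change of cold against room temperature in control (horizontal) and Ucp1 knockout rats (vertical), 1 point per gene, with equality dotted. Black points passed in both genotypes (35 genes); Scd, Thrsp and Fasn lie above the dotted line at 4.80, 3.33 and 3.13 in knockouts against 2.13, 1.36 and 1.58 in controls.

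The test of the difference itself, the interaction of genotype and cold, called 0 genes by edgeR's quasi-likelihood test; 737 genes had an unadjusted p under 0.05, and DESeq2 called 1, Bhlhe41. By edgeR the 5 smallest p-values of genes with a symbol belonged to Bhlhe41, Ddhd2 (-1.85 ± 0.46), Tmem131 (-1.74 ± 0.44), Thrsp (1.97 ± 0.51) and Tigd4 (-1.80 ± 0.47). All but Bhlhe41 had adjusted p = 0.452, and of the 5 only Thrsp had a positive difference between the cold effects. Scd (2.67 ± 0.90, adjusted p = 0.538), Fasn (1.56 ± 0.61, adjusted p = 0.597) and Mt-atp8 (-1.002 ± 0.34, adjusted p = 0.538) ranked below them. These are given for their changes in cold knockouts. The smallest adjusted p was that of Bhlhe41, 0.125 with a difference of -1.75 ± 0.34; its level went from 7.38 ± 2.56 to 14.5 ± 4.34 CPM in controls and from 11.02 ± 3.15 to 6.41 ± 2.29 CPM in knockouts. Among the lists, lipogenesis differed towards a larger cold response in knockouts at the preset correlation, with 3 of 14 members adjusted over the list alone (camera adjusted p = 0.00606; adjusted p = 0.379 with an estimated correlation). The contraction-induced immediate response, with a median change of -0.57 in controls and -0.04 in knockouts, differed as well, with 0 of 19 members adjusted over the list alone (camera adjusted p = 0.0146; adjusted p = 0.956 with an estimated correlation). Neither list passed by fry. Nor did either pass at the preset correlation without the 7 libraries at the low end of the first principal component (adjusted p = 0.239 and 0.192). On simulated data, with genes drawn independently, this test recovered 23.9% of 2-fold differences.

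Between knockout and control muscle at room temperature, edgeR's quasi-likelihood test called 0 genes, with 712 at an unadjusted p under 0.05 where 504 are expected. DESeq2 called 1, Ech1. Ech1, an enzyme of unsaturated fatty acid oxidation, had the smallest p (0.57 ± 0.12, adjusted p = 0.237; 127 ± 22.6 CPM in 8 controls and 189 ± 18.8 CPM in 7 knockouts). It was followed by Lgi3 (-3.77 ± 0.89), Pik3cd (-1.004 ± 0.24), Gpx3 (0.68 ± 0.17), a secreted peroxidase, and Prp2l1 (-1.17 ± 0.31). Without control animals 1 and 2 Pik3cd was at -0.41 and Prp2l1 at -0.85. At the preset correlation the lists of fatty acid uptake and oxidation (camera adjusted p = 1.21e-05; adjusted p = 0.146 with an estimated correlation) and of satellite cell, regeneration and denervation genes (0.0268; adjusted p = 0.146 with an estimated correlation) were higher in knockouts. Fast glycolytic fibre (0.0141) and glycolysis genes (0.0151) were lower, each at adjusted p = 0.865 with an estimated correlation. Immune markers were higher beside them, with 19 of 20 positive and 0 passing when adjusted over the list alone (camera adjusted p = 1.82e-07; adjusted p = 0.266 with an estimated correlation). Fry called 0 lists in this contrast. Without control animals 1 and 2 the immune (adjusted p = 0.344), satellite cell (0.113), fast fibre (0.284) and glycolysis lists (0.510) did not pass at the preset correlation, and the fatty acid list did. Adjusted over the list alone, Decr1 (0.82 ± 0.23), an enzyme of unsaturated fatty acid oxidation, and Pdk4 (1.42 ± 0.43) were higher among 34 fatty acid genes and Pfkfb3 (-1.11 ± 0.31), a regulator of glycolysis, was lower among 24 glycolysis genes.

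In the cold 1 gene differed between genotypes. Ntf4, the neurotrophin NT-4 (GRCr8 chromosome 1, 105030035 to 105032866), was lower in knockouts, at 1.61 ± 0.277 against 3.20 ± 0.698 CPM (SD, n = 8 and 8), a log2 change of -0.99 ± 0.17 (SE; edgeR quasi-likelihood adjusted p = 0.0310). The next were Bhlhe41 (-1.17 ± 0.24), the heme-degrading enzyme Hmox1 (1.14 ± 0.23) and Thrsp (1.70 ± 0.35), each with adjusted p = 0.0906, and Tigd4 (-1.39 ± 0.33, adjusted p = 0.242). In all 633 genes had an unadjusted p under 0.05 where 504 are expected, and DESeq2 called 8, Ntf4, Bhlhe41, Hmox1, Thrsp, Ucp2, Tigd4, Angptl8 and 1 gene without a symbol. Of 14 lipogenesis genes 0 passed over all genes and 4, Thrsp, Acly (0.86 ± 0.21), Scd (1.91 ± 0.56) and Fasn (1.35 ± 0.41), were higher when adjusted over the list alone (camera adjusted p = 5.11e-05; adjusted p = 0.0680 with an estimated correlation). Beside them 12 of 13 white adipocyte markers and 6 of 6 erythrocyte markers had higher values in knockouts, and 0 passed when adjusted over the list alone (camera adjusted p = 2.86e-05 and 0.0205; adjusted p = 0.249 and 0.339 with an estimated correlation). All 13 measured fast fibre genes, without Myh4 and Atp2a1 among them, and all 12 mitochondrially encoded transcripts had lower values in knockouts (camera adjusted p = 2.86e-05 each, and 0.324 and 0.249 with an estimated correlation). Of the fast fibre genes 1, Myh1, was lower when adjusted over the list alone. In total 13 lists passed at the preset correlation, 0 with an estimated one and 0 by fry. The others were satellite cell, atrophy and autophagy, contraction-induced, heat shock, immune and fatty acid lists, higher in knockouts, and glycolysis and calcium cycling, lower. Immune markers had 16 of 20 values higher. Without the 7 libraries at the low end of the first principal component 6 of these 13 lists did not pass at the preset correlation, among them lipogenesis (adjusted p = 0.134) and the erythrocyte markers (0.467). The call of Ntf4 ended in 10 of 31 omissions of single libraries (highest adjusted p = 0.179) and without the 7 libraries at the low end of the first principal component (-0.90, adjusted p = 0.256).

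Averaged over temperatures, edgeR called 0 genes for the knockout, with 645 at an unadjusted p under 0.05 where 504 are expected, and DESeq2 called 9, among them Ech1, Hmox1, Nqo1 and Ntf4. The smallest p-values of genes with a symbol belonged to Nqo1, a quinone reductase (0.74 ± 0.15, adjusted p = 0.0898), Ntf4 (-0.60 ± 0.12, adjusted p = 0.0898), Ech1 (0.37 ± 0.08, adjusted p = 0.151), Hmox1 (0.75 ± 0.17, adjusted p = 0.187) and a copy of Rpl30 (-1.14 ± 0.27, adjusted p = 0.265). The list of satellite cell, regeneration and denervation genes was higher in knockouts, with 10 of 13 positive (camera adjusted p = 1.60e-04; adjusted p = 0.00433 with an estimated correlation). Within it 0 genes passed over all genes and 3 were higher when adjusted over the list alone, Runx1 (0.58 ± 0.15), a transcription factor induced by denervation, Cdkn1a (0.84 ± 0.23), the cell cycle inhibitor p21, and the cardiac actin Actc1 (0.73 ± 0.23). In total 13 lists passed at the preset correlation, and this 1 with an estimated correlation. Immune markers were higher in 19 of 20 cases beside it (camera adjusted p = 2.32e-09; adjusted p = 0.107 with an estimated correlation). Without the 7 libraries at the low end of the first principal component the satellite cell list stood at adjusted p = 0.182 with an estimated correlation.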

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

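The first principal component as a covariate was added as a setting after the data were seen, and the measures examined here include genes that the naming rule chose from the results. In each of 120 sets (30 measures in 4 groups) the highest and lowest animals were set against the rest of their group, and 4 stood far from it by Dixon's criterion, where chance gives about 5% of sets. Each is reported as a measured value, and no animal was left out for it.

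Pdk4, the kinase that shuts off pyruvate dehydrogenase, stood at 0.223 CPM in cold control 16, below the 1.21 to 3.24 CPM of the other cold controls. Atp2a2, the calcium pump of slow fibres, stood at 421 CPM in cold knockout 31, where the other cold knockouts had 897 to 1601 CPM. Fos stood at 94.98 CPM in control 8 at room temperature, above the 13.5 to 30.4 CPM of the others. Its fall in cold controls ranged from -2.33 to -1.60 on the log2 scale without single libraries, and its call held in all 31 omissions. Mss51, a mitochondrial gene of fast muscle, stood at 27.4 CPM in cold knockout 29, below the 79.9 to 184 CPM of the other cold knockouts. For these single values no explanation was tested.

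The cold response of 2 gene lists differed between genotypes in the test of the interaction at the preset correlation. These were lipogenesis (camera adjusted p = 0.00606, median log2 difference 0.43, 12 of 14 members positive) and the contraction-induced immediate response (camera adjusted p = 0.0146, median 0.65, 16 of 19 positive). With an estimated correlation they stood at adjusted p = 0.379 and 0.956, and no single gene passed the interaction in edgeR's quasi-likelihood test (737 at an unadjusted p under 0.05, 1 by DESeq2).

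The lipogenic response of cold knockout rats, with a median log2 change of 3.23 over Acly, Fasn, Scd and Thrsp, was set against 3 technical explanations. More fat cells in the muscle piece could raise these genes, and the adipocyte score, the mean log2 level of 12 markers, was 4.82 ± 0.490 in cold knockouts and 4.04 ± 0.310 in room temperature knockouts (SD). With that score as a covariate the median was 2.52 and 4 of 4 genes passed. Scd went from 4.80 to 2.84 and Acly stayed at 0.97. The score is a rough measure of fat cells, so what it leaves cannot exclude them. Of its markers, whose median change was 0.86, Gpd1 (-0.03), Aqp7 (0.05), Lipe (0.20) and Fabp4 (0.25) changed little. Of these, Gpd1 is also on the fast fibre list, and Lipe and Fabp4 are on the list of fatty acid uptake and oxidation. All other markers of the score had larger increases, from 0.801 for Cebpa to 2.41 for Retn. Among them were Adipoq (1.47), Plin1 (1.32) and Cidec (1.25), and only Retn passed over all genes. Room temperature controls 1 and 2 scored far below all others (1.81 and 1.63) and weigh on the fit. With the first principal component as a covariate the median was 3.13. The knockout groups hardly differed on it (mean 0.826 at room temperature, 1.38 in the cold), so this adjustment could change little. Without single cold knockout libraries the median ran from 2.98 to 3.37, so no single animal carried it, though such omissions cannot test several animals. Cold knockouts 24, 29 and 31 stood lowest of their group, at log2 CPM of 2.39, 1.88 and 3.84 for Scd. For Fasn they stood at 3.84, 2.73 and 2.46, where the others started at 5.28 for Scd and 4.72 for Fasn. Their adipocyte scores were the lowest of the group too (4.10, 4.33 and 4.43). Without the 7 libraries at the low end of the first principal component the 4 genes still passed. Scd was then at 4.64, Thrsp at 2.71, Fasn at 2.51 and Acly at 0.73, and the list stood at adjusted p = 0.103 with an estimated correlation. More fat cells in the piece and a change within them stay open, as does a response of muscle fibres to cold. Counts of whole muscle do not show which cells made the transcripts.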

How the results depend on the processing

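Of the settings reported here, 3 were chosen after the data were seen: leaving out room temperature controls 1 and 2, leaving out the 7 libraries at the low end of the first principal component, and that component as a covariate. No named gene that passed turned direction under any setting run; among lists that passed, erythrocyte markers in the averaged knockout effect were lower instead of higher without the low-end libraries, without passing (camera adjusted p = 0.961). Cold in controls called 86 genes, and 220 with DESeq2, 687 with voom, 383 with 1 surrogate variable, 38 without room temperature controls 1 and 2, 53 without the low-end libraries and 379 with the component as a covariate. Leaving out single libraries gave 36 to 154, moving beyond 1.5 times the count without room temperature controls 1 (53), 2 (43) and 4 (154) and cold controls 17 (56), 20 (45), 21 (36) and 22 (52). Cold in knockouts called 139 genes, and 328 with DESeq2, 53 with only the groups compared, 536 with voom, 651 with 1 surrogate variable, 379 without room temperature controls 1 and 2 and 674 with the component as a covariate; without the low-end libraries it called 146, of which 79 were among the 139. Single omissions gave 56 to 231, and the count moved that far without room temperature controls 1 (219) and 2 (231), room temperature knockouts 9 (90), 11 (86), 13 (79) and 14 (56), cold control 17 (213) and cold knockouts 28 (230) and 30 (80). The surrogate variable correlated with the first component (r = 0.997), so the settings that model it share a source; for the other shifts the cause was not tested.

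The knockout at room temperature called 0 genes, 1 with DESeq2 and 0 to 1 without single libraries (1 without room temperature control 3). The knockout in the cold called 1 gene, 8 with DESeq2, 0 with only the groups compared, 5 with 1 surrogate variable, 4 without room temperature controls 1 and 2, 0 without the low-end libraries, 8 with the component as a covariate and 0 to 3 without single libraries. Voom called 1 gene too, Tigd4 and not Ntf4, and the call of Ntf4 ended without room temperature control 4, room temperature knockout 9, cold controls 17, 19, 20 and 23, and cold knockouts 25, 26, 29 and 30. The interaction called 0 genes, 1 with DESeq2, 4 with voom and 0 to 1 without single libraries (1 without room temperature control 6, cold control 16 or cold knockout 28). The knockout averaged over temperatures called 0 genes, 9 with DESeq2, 11 with voom, 7 with 1 surrogate variable, 1 without room temperature controls 1 and 2, 8 with the component as a covariate and 0 to 2 without single libraries (2 without room temperature knockout 14, 1 without cold knockout 27). The correlation of the cold effects was 0.353, 0.786 over called genes only, and 0.241 to 0.426 without single libraries (jackknife SE 0.232). Without the 20 most abundant genes in the library sizes the calls in cold knockouts were 96 higher and 56 lower, against 103 and 36, and the balance of calls turned to 72 and 92 without room temperature knockout 15. In controls it turned from 60 higher and 26 lower to 159 and 224 with 1 surrogate variable. Sln, which did not pass in either genotype, passed for cold in both with voom, with 1 surrogate variable, without the low-end libraries and with the component as a covariate (highest adjusted p = 0.0486). Of 26 lists, camera at the preset correlation called 13 for cold in controls and 9 for cold in knockouts. It called 5, 13 and 13 for the knockout at room temperature, in the cold and averaged, and 2 for the interaction. With an estimated correlation 2 and 5 of these still passed for cold, 1 for the averaged knockout and 0 for the others. Fry called 6 lists for cold in each genotype, 1 for the averaged knockout and 0 for the others. Thus 47 passing results were lost with an estimated correlation and 43 with fry. With DESeq2 size factors 0 of 156 list results crossed the threshold. What depth limits was not tested, since no setting varied it. The simulation used the depth and spread of these libraries but drew genes independently. In it the recovery of 1.5-fold changes was 20.9% for cold in controls and 4.48% for the interaction.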

Other observations

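Chosen after the results were seen were the tests of the first principal component against the group of the animal and as a covariate, and the permutation of the spread of mitochondrial transcripts. The genes of the next paragraph were also chosen after their values were seen.

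Some of the 35 genes called for cold in both genotypes are given here as single values, with no test of a shared function. Slc2a5, the fructose transporter, rose by 1.14 in controls and 1.31 in knockouts on the log2 scale, and Khk, which phosphorylates fructose, by 1.10 and 1.18. Bdh1, which interconverts the ketone bodies, rose by 1.48 and 1.80, and Ldhb, the lactate dehydrogenase subunit of oxidative tissue, by 0.85 and 0.75. Tnni3, the cardiac troponin I, rose by 2.28 and 2.74, Enho, which encodes the peptide adropin, by 1.12 and 1.33, and the peroxidase Gpx1 by 0.77 and 0.69. The calls of Bdh1 and Enho held in both genotypes without any single library. Those of Tnni3 and Khk ended in 8 and 11 of 31 omissions in controls, where Tnni3 was at 1.504 without cold control 21, and that of Ldhb in 26 in knockouts. Without room temperature controls 1 and 2 the calls of Tnni3, Khk and Ldhb in controls ended (adjusted p = 0.0645, 0.0512 and 0.0579). Without the 7 libraries at the low end of the first principal component those of Khk in controls (0.135) and of Ldhb (0.125) and Gpx1 (0.0836) in knockouts ended.

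Transcripts encoded in mitochondrial DNA were lower in the cold by a mean log2 change of -0.47 over both genotypes (95% interval -0.65 to -0.30, 12 transcripts). With the first principal component as a covariate the mean was -0.46 (-0.64 to -0.29). That component did not part the groups (permutation p = 0.847 for its between-group sum of squares). The adjustment could therefore change the mean little, and no conclusion is drawn from it. A single shift of all of them, such as fewer mitochondrial transcripts caught alike, would give equal changes, but they spread beyond their errors (heterogeneity p = 1.09e-07; permutation p = 1e-04, the smallest that 10000 permutations can give). Mt-co1 changed by -0.03 in controls and -0.22 in knockouts, and Mt-nd4l by -1.01 and -1.14. Mt-atp8 changed by -0.40 and -1.40, and Mt-atp6 by -0.14 and -0.23. Mt-nd4 was not among the 12 transcripts measured. Counts are per gene and do not show from which mRNA or tail a read came. A spread between genes therefore need not be one between separate mRNAs. A change in mitochondrial transcript processing or stability may underlie this, as may unequal priming of their tails by the 3' method, and neither was tested.

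Libraries of every group parted along the first principal component, and 7 lay at its low end: room temperature control 1, room temperature knockouts 9 and 12, cold controls 17 and 23 and cold knockouts 25 and 28. The group of the animal did not explain the score (permutation p = 0.847). Its correlation was -0.29 with total counts (95% interval -0.58 to 0.07) and -0.40 with the share of the 20 most abundant genes (-0.66 to -0.05), and these intervals leave both open as part of the cause. Endothelial markers had the strongest relation of the cell type lists (r = -0.48), short of the 0.7 that would be needed to carry most of the score. The score correlated with the contraction-induced response (r = 0.803), heat shock proteins (r = 0.800), the tricarboxylic acid cycle (r = 0.728), fast fibre genes (r = -0.73) and glycolysis (r = -0.70). A difference in muscle activity, sampled region or handling before freezing could be involved, but these lists do not single out any of them and none is recorded in the labels.

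Other splits of the animals, 100 in each comparison with the real one, gave at most 9 genes for cold in controls (real 86, 1 of 100 splits as large). They gave at most 75 for cold in knockouts (real 139, 1 of 100). No other split reached the real count in either, and 1 of 100 is the smallest share that so few splits can give. The split with 75 genes had the largest difference in the first principal component, with 0 and 4 low-end libraries on its sides. For the knockout in the cold 2 of 100 splits called at least 1 gene (real 1, highest other 1). Since the adjustment itself lets few splits call any gene, this adds little to the call, and the call of Ntf4 ended under several settings. For the 3 counts of 0 the splits say nothing about chance, since any split gives at least 0 genes and 100 of 100 was fixed in advance. The highest others were 2 for the knockout at room temperature, 1 for the interaction and 1490 for the knockout averaged over temperatures. The split with 1490 genes put 6 of the 7 low-end libraries on 1 side, which points to a structure of the samples.

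A difference in the DNA flanking Ucp1, carried along with the knockout, could change its neighbours. Of the 20 nearest tested genes, 10 on each side, 1 had an unadjusted p under 0.05 for the averaged knockout effect, Gipc1 (0.28 ± 0.11). The median of 8948 windows of 20 genes was 1 as well, and 74.8% of windows held as many or more. That argues against an effect across the region alike at both temperatures, but not against one on a single neighbour. Rnf150, the first tested gene after Ucp1, had a called fall in cold knockouts (-1.16 ± 0.17). Its level in knockouts and controls was 24.1 and 20.1 CPM at room temperature and 10.8 and 16.4 CPM in the cold. These differences have opposite signs and offset each other in the average (-0.17 ± 0.12).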
